A study of Mus musculus with 6 samples.

How the data were processed

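RNA of sorted leukaemia cells was hybridised to Affymetrix mouse genome arrays, with 3 arrays of MycGFP negative and 3 of MycGFP positive cells. Per the labels' protocols, mononuclear cells of the spleen were sorted from congenic recipients by mCherry and GFP. Total RNA, 5 ng per sample, was then amplified with the Ovation system before biotin labelling, per the labels' protocols. Amplification from so little RNA can favour the 3' ends of transcripts and adds noise to dim genes, so the 3' to 5' ratios of control probe sets are given with the data. The deposited values are intensities on a linear scale, summarised per probe set with RMA per the submitters' processing notes, whose version is not given in the sources used here. The values were checked to be linear: all were above 0, the array minima were 2.89 to 3.2 and the maxima 18767 to 19948 without control probe sets. RMA usually yields log2 values, and the test had been planned for these, so log2 of the deposited intensity was taken first and the planned test kept. RMA scales arrays to one another, so a change in total RNA per cell is not visible. No detection calls were used, so a gene near the array median of about 32 may be background, and a fold against such a level is uncertain.

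Probe sets were named from the platform annotation given for the array, with symbols looked up by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, where 34754 probe sets matched. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9160 others had none; the 64 control probe sets were left out. No gene was named from a probe set with several symbols, and no coordinates are given, since neither the labels nor the deposited values name a genome build and that table was used only for names. Each of 18193 gene symbols was represented by the probe set with the highest mean over all 6 arrays. Another probe set existed for 663 of the 1115 called genes. For 150 of these some other probe set had a difference of opposite sign, and for 4 it passed the test the other way.

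Groups were taken from the sample titles. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual and 2.17 prior degrees of freedom. Log2 differences are MycGFP positive minus negative, with limma's moderated SE. Folds are the antilog of these differences, so they are ratios of geometric means. Mean intensities are arithmetic, so their ratio differs from the fold. Fixed before the data were examined were 35 gene lists with 857 different symbols, of which 786 were measured. They were tested with camera from limma at its preset correlation of 0.01, with adjustment over the 35 lists, each of at least 5 measured genes. Counts of list members that pass are given over all genes and adjusted over the list alone. Several lists share genes, so their calls are not independent. The T cell, MHC and marker lists do, as does quiescence with mature naive T cells and with immediate early genes. So do p53 targets with the BCL2 family, and nucleotide metabolism with the unfolded protein response. The rule for named genes, also fixed before the data were examined, took Myc, the 12 largest rises and 12 largest falls among called genes with separated groups, leaving out gene models and receptor segments, then up to 4 called members per list with the smallest adjusted p, or the 2 largest differences of a list with none.

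The array numbers were checked for pairing, since the design describes 3 leukaemias that were each sorted and both groups are numbered 1 to 3. After subtracting the group means, arrays of the same number correlated across genes with r = 0.38, 0.21 and 0.39, and arrays of different number in the other group with r = -0.32 to -0.03. Genes are not independent replicates, so these values only describe the arrays. The deviations within a group also cancel for every gene, so positive values for arrays of the same number force some negative values for the others. The contrast is thus partly built in. The second principal component, with 24.3% of the variance, separated the numbers rather than the groups, and the third, with 14.8%, set the arrays numbered 2 apart but did not separate numbers 1 and 3. No label says that a number marks one leukaemia. The Y-linked gene Eif2s3y, which bears on this, differed within numbers, with intensities of 1038 and 125 on negative and positive array 2 and of 40.2 and 186 on those numbered 3. By the correlations the numbers were taken, as an assumption, to pair the arrays, and the fit with the number as a block is given beside a result where it changes the call. Under the block 1047 genes were higher and 354 lower, and 892 genes were called in both fits. The p-values measure the spread between these sorted samples of 3 leukaemias.

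Alternatives were the block, each array left out in turn, the mean of all probe sets of a gene, every probe set tested on its own, cross-hybridising probe sets left out, the dimmest 40% of genes left out, quantile normalization, median centring, cyclic loess, a trended and robust variance, array weights, a minimum log2 difference of 1, camera with an estimated correlation, and fry. Leaving out both arrays of a number was added after the data were seen. The procedure was tested on simulated data with the means and spreads of these 18193 genes. Over 5 simulations it recovered 80.9% of planted log2 differences of 2, 13.4% of those of 1 and none of 335 of 0.58, with 26 false calls in all. A list shifted by 0.5 was called in 5 of 5 simulations, and none of 170 tests of the other lists passed. The simulated genes varied independently of each other, so this says nothing of lists whose genes vary together. Fewer genes were planted in each simulation than the 1115 called in the data. The adjustment depends on that number, so the recovered shares may not carry over to the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.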

Results

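The series profiled T-cell acute lymphoblastic leukaemia (T-ALL) driven in mice by Notch1ΔE, an activated form of the NOTCH1 receptor, on a c-Myc-GFP background in which GFP reports the MYC protein. CD25+ splenocytes were taken from 12-week-old C57BL/6 mice 4 weeks after transplantation and sorted by GFP into MycGFP negative and MycGFP positive cells. Each group held 3 arrays, numbered 1 to 3, and the design describes 3 independent leukaemias that were each sorted. The comparison asks how the transcripts of MycGFP positive leukaemia cells, which the title of the series calls initiating cells, differ from those of MycGFP negative cells. Each array measured 45101 probe sets, and the median intensity lay between 30.5 and 32.7 on all 6 arrays. Pearson's r across the 18193 genes was 0.969 to 0.977 among the negative arrays, 0.979 to 0.989 among the positive arrays and 0.953 to 0.972 between the groups. The first principal component held 45% of the variance and separated the groups, with the negative arrays at -54.8 to -34.1 and the positive arrays at 35.5 to 53.5. The ratio of the 3' to the 5' control probe sets of Gapdh, a sign of RNA quality, was 1.58 to 1.89 on negative and 1.48 to 1.58 on positive arrays. The same ratio for actin overlapped between the groups, at 1.54 to 1.87 and 1.72 to 1.85. The number of arrays limits the precision of every value.

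Myc itself, the gene whose protein the sort selected on, was 2.58-fold higher in MycGFP positive cells. Its intensity was 1080 ± 256 (SD, n = 3) in negative cells, with single values of 801, 1135 and 1303. In positive cells it was 2764 ± 571 (SD, n = 3), with single values of 2628, 3390 and 2274. The log2 difference was 1.37 with an SE of 0.24 (limma, adjusted p = 0.0329), and all 3 positive values lay above all 3 negative ones. Mxd4, which pairs with the MYC partner MAX and represses transcription, was 2.75-fold lower (adjusted p = 0.0438). These were the only members of the MYC-MAX network list that passed among 12, and 1 member rose and 3 fell when adjusted over the list alone. The list as a whole was not called by camera, a set test (adjusted p = 0.115). The call for Myc was lost without positive array 1 (adjusted p = 0.0913), positive array 2 (0.108), positive array 3 (0.0786) or negative array 2 (0.0952), with log2 differences of 1.39, 1.21, 1.496 and 1.42.

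**Figure D1:**
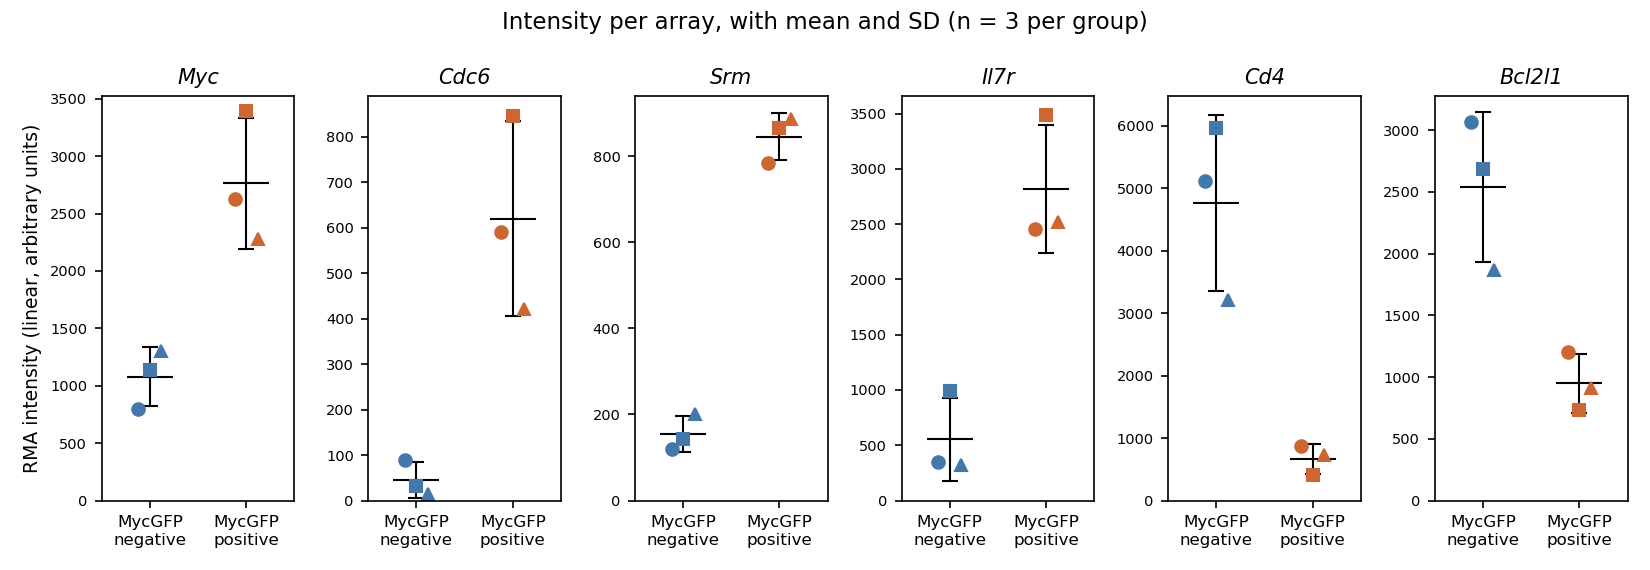
Linear RMA intensity of Myc, Cdc6, Srm, Il7r, Cd4 and Bcl2l1 on each array, with circles, squares and triangles for the arrays numbered 1, 2 and 3 and black bars for the mean and SD of 3 arrays. Myc lies between 801 and 1303 in MycGFP negative and between 2274 and 3390 in MycGFP positive cells, and Cd4 shows the opposite order.

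Across 18193 genes, 840 were higher and 275 lower in MycGFP positive cells at an adjusted p under 0.05 (limma, two-sided), so 75.3% of the called genes were higher. A log2 difference of at least 1 was reached by 647 of the higher and 198 of the lower genes. For each called gene the 3 values of one group lay above the 3 of the other, a separation found in 28.1% of all genes where chance gives 10%. Cdc6, which loads the replicative helicase, rose 17.4-fold (adjusted p = 0.028), from 45.2 ± 39.6 to 619 ± 214 (SD, n = 3). Mcm10, another helicase factor, rose 12.5-fold, and Pole, the catalytic subunit of DNA polymerase epsilon, rose 9.14-fold. Genes of the kinetochore and spindle checkpoint, Zwilch, Ska1, Trip13 and Cenpi, rose by 12.3-fold, 11.5-fold, 10.9-fold and 9.59-fold. Rad54b, a recombination gene, rose 11.6-fold. The dCMP deaminase gene Dctd rose 8.87-fold, Rnf227 8.89-fold, Fam183b 11.5-fold and Nsmf 10.04-fold. Mean intensities of Dctd, Rnf227, Nsmf and Cenpi in negative cells were 16.9, 19.6, 10.6 and 29.1, below the array medians, and those of Ska1 and Fam183b, 33.5 and 33.4, lay at the medians, so these folds compare a signal with near background. Cdc6 also lay below the median on negative arrays 2 and 3, at 31.5 and 14.2, as did Mcm10 (25.5) and Rad54b (27.8) on negative array 3. Nsmf rested on 1 cross-hybridising probe set, and without such probe sets its log2 difference was 0.39 (adjusted p = 0.182). Of the other Ska1 probe sets, one gave a log2 difference of 1.48 (adjusted p = 0.0267 over all named probe sets) and one, also dim, -0.07.

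The largest falls were those of Ston2, an endocytic adaptor, at 22.01-fold lower (adjusted p = 0.0191), and Tm4sf5, a tetraspanin-like membrane protein, at 21.2-fold lower (adjusted p = 0.0277). Ston2 went from 2252 ± 1316 to 97.0 ± 50.6 and Tm4sf5 from 863 ± 624 to 34.6 ± 17.1 (SD, n = 3). Cd4, the co-receptor of helper and double positive T cells, fell 7.26-fold, from 4764 ± 1413 to 667 ± 238 (SD, n = 3). Dhrs3, a retinaldehyde reductase gene, was 13.3-fold and Tcf7l2, a TCF transcription factor, 9.65-fold lower. Patj, a cell polarity gene, fell from 308 ± 92.3 to 29.98 ± 3.45 (SD, n = 3). Adamts6, Xkrx, Camk2n1, Gabbr1, Zfyve28 and Ramp3 were 6.55-fold to 9.08-fold lower. Adamts6, Camk2n1, Ramp3 and Patj had mean intensities of 6.92, 12.7, 29.4 and 29.98 in positive cells, under the array medians. Tm4sf5 was under them on positive arrays 2 and 3, at 20.02 and 30.4, and Tcf7l2 on positive array 2, at 18.9. With the array number as a block, Dhrs3 (adjusted p = 0.0507) and Gabbr1 (0.0785) no longer passed.

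**Figure D2:**
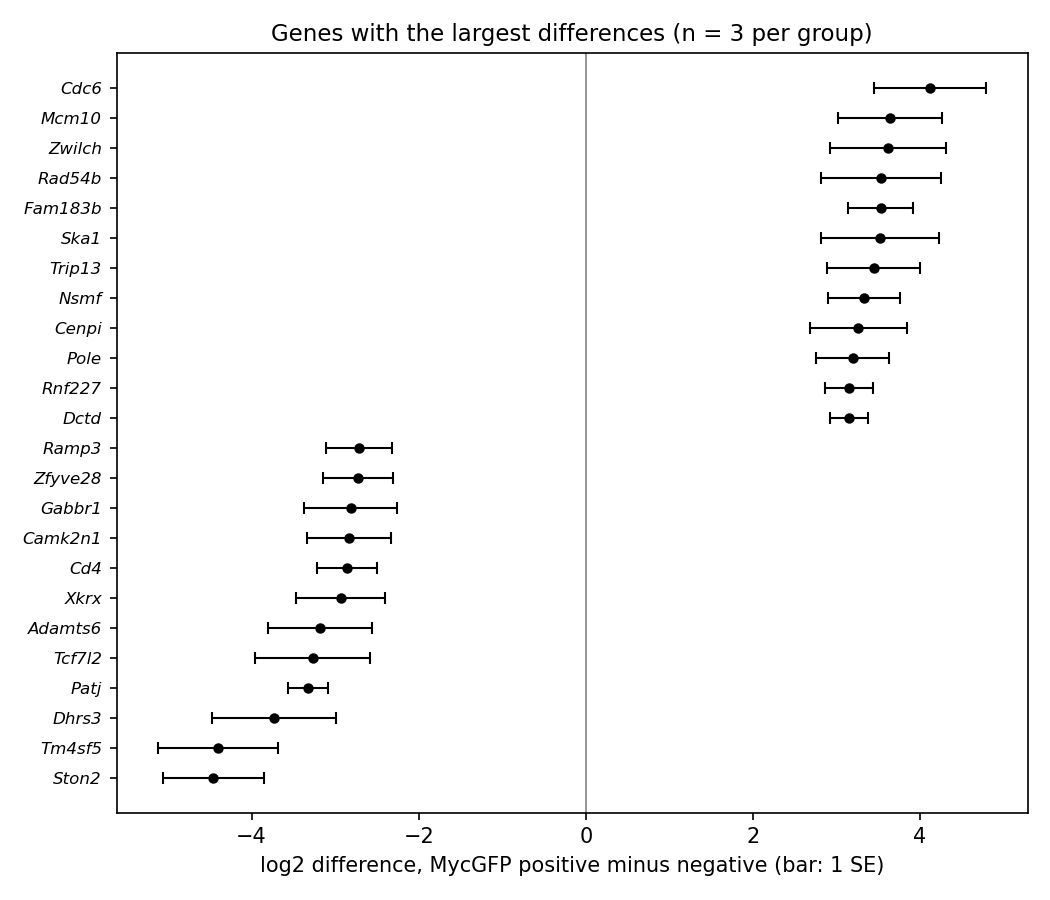
Log2 difference of MycGFP positive minus negative cells, with 1 SE, for the 12 genes with the largest rise and the 12 with the largest fall among named genes past the test. The rises run from 3.15 for Dctd to 4.12 for Cdc6, and the falls from -2.71 for Ramp3 to -4.46 for Ston2.

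The counts depended on single arrays. Without positive array 2, limma called no gene, the smallest adjusted p being 0.0591, although 2209 genes were higher and 976 lower at an unadjusted p under 0.05. That array ends every gene call given here. Without positive array 3, 104 genes were higher and 26 lower, without positive array 1, 174 and 55, and without negative array 2, 131 and 37. Without negative array 1, 862 were higher and 176 lower. All 1115 called genes kept the sign of their difference without any one of the 6 arrays, but their separated groups fix this in advance, so it is no support. Centring each array on the median over its genes moved the median log2 difference of all genes from 0.01 to -0.14. It gave 502 higher and 381 lower genes, so that 56.9% were higher. Among genes named here that step ended the calls of Rad54b, Ska1, Kif23, Ndufab1, Cox5a, Atp5b, Phlda3, Bid, Oasl2, Pdia6 and Irf8, at adjusted p of 0.0501 to 0.074. Averaging all probe sets of a gene ended those of Mrps2, Kif23, Ndufab1, Fdps, Bcl2l1, Bcl2l11, Ciita, Ctsl and Irf8, at adjusted p of 0.051 to 0.187.

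Of 33 measured genes widely described as MYC targets, 21 rose, 27 when adjusted over the list alone, at a median log2 difference of 1.13. Srm, which makes spermidine, rose 5.60-fold (adjusted p = 0.0103), and the serine hydroxymethyltransferase genes Shmt1 and Shmt2 rose 5.29-fold and 3.95-fold. Cad, whose product starts pyrimidine synthesis, rose 5.12-fold. Of 56 genes for ribosome biogenesis, 26 rose, and 40 rose and 1 fell when adjusted over the list alone, at a median log2 difference of 1.09. The latter, named after its values were seen, was Wdr12, at a log2 difference of -1.05 (adjusted p = 0.0751 over all genes). Those that rose included the nucleolar genes Nop58 at 3.51-fold, Gnl3 at 3.77-fold, Heatr1 at 3.30-fold and Rrp12 at 4.03-fold higher. Rrp12 lay below the array median on negative array 2, at 26.4. Camera, which sets a list against all other genes, gave adjusted p = 6.27e-17 for the MYC targets and 4.08e-20 for ribosome biogenesis at its preset correlation. With an estimated correlation both had adjusted p = 0.0868. The list of cytosolic ribosomal proteins was not called (camera adjusted p = 0.0871), at a median log2 difference of 0.11. Of 28 measured, Rpl14 alone rose, 3.56-fold, and 3 were higher at an unadjusted p under 0.05. That list was called higher in 6 of 20 other settings: without negative array 3 (adjusted p = 0.0105), positive array 1 (0.0393) or both arrays numbered 3 (0.0386), without cross-hybridising probe sets (0.032), with a trended and robust variance (0.0108) and with array weights (0.0396).

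The 6 arrays also gave list calls under other groupings, where camera at its preset correlation called 10 to 18 of the 35 lists, against 10 higher and 8 lower for the sorted groups. With an estimated correlation camera called none of the 35 lists, with 4 higher and 5 lower at an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way, called 8 higher and 7 lower.

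Of 38 genes for S phase and DNA replication, 24 rose, 34 when adjusted over the list alone, and the median log2 difference was 2.19. The helicase gene Mcm6 rose 5.89-fold, the licensing factor gene Cdt1 3.83-fold, the DNA polymerase delta gene Pold1 5.35-fold and the transcription factor gene E2f1 5.17-fold. Of 39 genes for G2 and mitosis, 5 rose over all genes tested and 37 when adjusted over the list alone, at a median log2 difference of 2.22. Among these, Anln, needed for cytokinesis, rose 8.54-fold, the checkpoint kinase gene Ttk 7.71-fold, Kif23, a kinesin gene, 3.91-fold and Foxm1, a transcription factor of mitotic genes, 3.15-fold. The fifth, named after its values were seen, was the mitotic kinase gene Plk1, which rose 4.68-fold. Anln lay below the array medians on negative arrays 2 and 3, at 27.6 and 13.7, and Ttk on negative array 3, at 23.2. The other Anln probe set, also dim, gave a log2 difference of 0.48 (limma, adjusted p = 0.256 over all named probe sets). Camera gave adjusted p = 1.13e-19 and 2.36e-15, and adjusted p = 0.208 and 0.370 with an estimated correlation. The negative arrays differed among themselves in these genes. On the scale of their own mean, the G2 and mitosis list lay at 1.29, -0.28 and -1.02 on negative arrays 1, 2 and 3, and at 2.54, 2.06 and 1.91 on the positive arrays. Fry did not call the G2 and mitosis list (adjusted p = 0.0699).

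Camera also called the metabolic lists higher at its preset correlation and none of them with an estimated one. Of 26 genes for nucleotide and one-carbon metabolism, 13 rose, 19 when adjusted over the list alone, among them Phgdh, which starts serine synthesis, at 4.23-fold, the pyrimidine gene Umps at 4.02-fold, and the purine genes Gart at 3.85-fold and Paics at 2.52-fold (camera adjusted p = 1.04e-12, and 0.127 with an estimated correlation). Of 26 genes for the mitochondrial ribosome and import, 11 rose, 20 when adjusted over the list alone. Timm8a1 rose 3.25-fold, Mrps28 2.81-fold, Tomm40 2.50-fold and Mrps2 2.42-fold (camera adjusted p = 4.17e-12, and 0.204 with an estimated correlation). Of 27 genes for oxidative phosphorylation, 6 rose, 12 when adjusted over the list alone, at a median log2 difference of 0.50 (camera adjusted p = 1.73e-08, and 0.205 with an estimated correlation). Atp5g1 rose 2.40-fold, Cox5a 1.84-fold, Ndufab1 1.78-fold and Atp5b 1.67-fold, the last with adjusted p = 0.0556 under the block. Of 23 genes for sterol and lipid synthesis, 7 rose, 10 when adjusted over the list alone (camera adjusted p = 0.000169, and 0.204 with an estimated correlation). The cholesterol pathway genes Sqle, Cyp51, Idi1 and Fdps were 4.69-fold, 4.22-fold, 3.69-fold and 2.28-fold higher. Of 25 genes for the unfolded protein and amino acid response, 6 rose, 10 when adjusted over the list alone (camera adjusted p = 0.00398, and 0.192 with an estimated correlation). Sdf2l1, Hspa5 and Pdia6, which fold proteins in the endoplasmic reticulum, rose 3.24-fold, 1.85-fold and 1.70-fold, and Slc7a5, an amino acid transporter gene, rose 2.74-fold. Of 18 glycolysis genes, 2 rose, and the same number when adjusted over the list alone: Hk2, a hexokinase gene, at 6.11-fold and Pgam1, a mutase gene, at 2.52-fold. The glycolysis list (camera adjusted p = 0.0278, and 0.397 with an estimated correlation) was no longer called without negative array 1 (adjusted p = 0.142) or positive array 2 (0.154), under fry (0.137) or in 5 other settings.

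**Figure D3:**
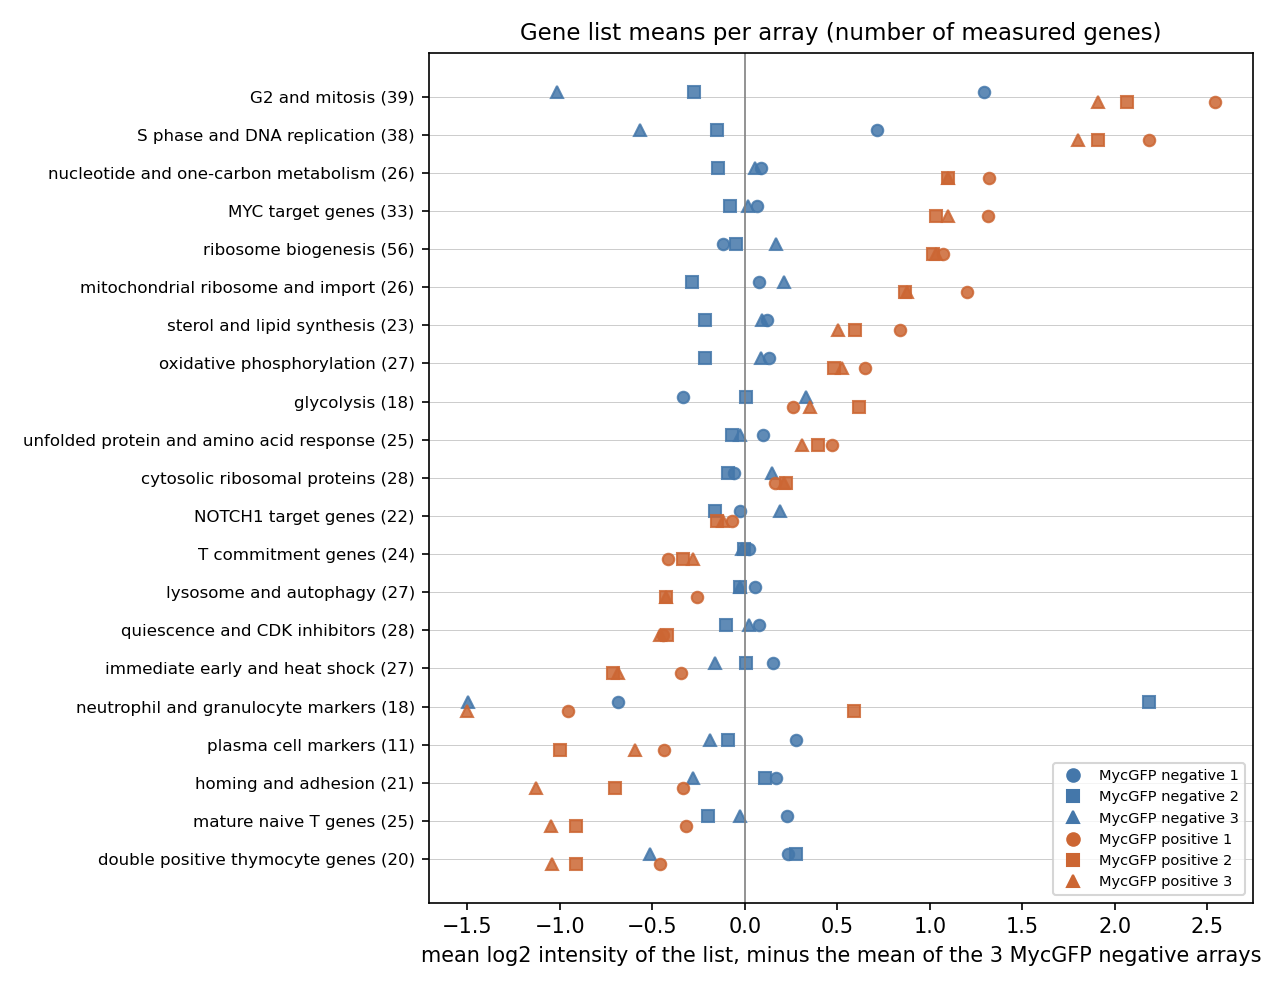
Mean log2 intensity of gene lists on each array, set against the mean of the 3 MycGFP negative arrays, with the number of measured genes in brackets, colours for the groups and symbols for the array numbers. The ribosome biogenesis list lies between -0.12 and 0.17 on negative and between 1.02 and 1.07 on positive arrays, while the neutrophil list is highest on the arrays numbered 2.

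Camera called the lists of mature naive T cells (adjusted p = 2.24e-06), double positive thymocytes (2.05e-05) and T commitment (1.06e-05) lower in MycGFP positive cells at its preset correlation. With an estimated correlation none of the 3 was called (adjusted p = 0.204, 0.204 and 0.189). Among 25 genes of mature naive T cells, 4 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone, at a median log2 difference of -0.97. Gimap6, a GTPase gene of lymphocytes, fell 3.20-fold, from 2200 ± 232 to 686 ± 38.1 (SD, n = 3). Foxo1, a transcription factor of resting T cells, fell 2.40-fold and Slfn2, which maintains T cell quiescence, 2.16-fold. Cd52, named after its values were seen, fell 5.62-fold. Il7r, the interleukin 7 receptor gene, rose 5.77-fold against the direction of the list. Among 20 genes of double positive thymocytes, 3 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone. Besides Cd4, Themis, a T cell receptor signalling gene, was 1.55-fold and Rmnd5a 1.98-fold lower, and Itm2a rose 3.44-fold. Among 24 genes of T commitment, Themis and Cd5 were lower, the latter 1.57-fold, and 6 were lower when adjusted over the list alone. Under the block, Themis and Cd5 had adjusted p = 0.0634 and Rmnd5a 0.0550.

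Of 28 genes for quiescence and CDK inhibitors, 5 fell over all genes tested, and 11 fell and 1 rose when adjusted over the list alone. Txnip, which limits glucose uptake, fell 2.53-fold and the antiproliferative gene Btg1 1.77-fold, from 12330 ± 696 to 6973 ± 631 (SD, n = 3). The others were Foxo1, Slfn2 and, named after its values were seen, Foxp1 at 1.62-fold lower, so no CDK inhibitor gene was among the 5. The immediate early gene Egr2 fell 5.27-fold and Zfp36, whose product destabilises mRNA, 3.26-fold, 2 of 27 on the immediate early and heat shock list, 4 when adjusted over the list alone. Of 21 homing and adhesion genes, Cxcr3, a chemokine receptor gene with mean intensities of 43.8 and 22.1, fell 1.98-fold and Itgal, the LFA-1 alpha chain gene, 1.79-fold, and both passed when adjusted over the list alone. Of 27 lysosome and autophagy genes, the cathepsin genes Ctsl and Ctsd fell 3.51-fold and 1.74-fold, and 3 fell when adjusted over the list alone. Camera gave adjusted p = 2.99e-05 for quiescence, 0.00032 for immediate early, 0.000367 for homing and 0.000114 for lysosome genes. With an estimated correlation each of these lists had adjusted p = 0.0868.

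The list of NOTCH1 target genes was not called (camera adjusted p = 0.138), with a median log2 difference of -0.19 over 22 genes. Il7r was the only member that passed, over all genes or adjusted over the list alone. Among 29 early T and stem progenitor genes, Slamf1 fell 4.55-fold and no other passed, over all genes or adjusted over the list alone. The list was not called (camera adjusted p = 0.362), and its median, 0.02, and mean, -0.10, differed in sign. Among 14 genes of the BCL2 family, 1 rose and 2 fell, and the same numbers when adjusted over the list alone. The anti-apoptotic gene Bcl2l1 fell 2.68-fold, from 2540 ± 610 to 948 ± 236 (SD, n = 3), Bcl2l11, which encodes the pro-apoptotic BIM, fell 2.07-fold, and Bid, also pro-apoptotic, rose 1.88-fold. The list as a whole was not called (camera adjusted p = 0.161). Among 25 p53 target genes, the death receptor gene Fas fell 5.03-fold and Phlda3, a dim gene at 17.2 and 40.2, rose 2.40-fold (0.0603 under the block), while 3 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.317). Among 31 interferon response genes, Igtp fell 2.29-fold and Oasl2, at 10.1 and 26.9 near background, rose 2.66-fold, the only 2 also when adjusted over the list alone (camera adjusted p = 0.161). Ciita, the regulator of MHC class II, fell 1.73-fold at intensities of 37.0 and 21.3 and was the only one of 18 MHC presentation genes to pass, over all genes or adjusted over the list alone (camera adjusted p = 0.121). Its other probe sets gave log2 differences of -0.10 and 0.00. None of 30 T effector and exhaustion genes passed with limma, over all genes or adjusted over the list alone, 2 being higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0871). Lag3 and Tnfrsf18 had the largest log2 differences there, -1.70 and -1.67 (adjusted p = 0.291 and 0.203). Other settings called some of these lists. The T effector list was called lower without positive array 1 (adjusted p = 0.000551) or both arrays numbered 1 (0.000528) and with array weights (0.0207). The MYC-MAX list was called lower without negative array 1 (0.0344) or both arrays numbered 1 (0.028) and with cyclic loess (0.0484). The interferon list was called lower without negative array 2 (0.0324), negative array 3 (0.0287), positive array 1 (0.0131) or both arrays numbered 2 (0.0413), while its mean log2 difference turned from -0.15 to 0.21 without negative array 1 and to 0.06 without positive array 3. The MHC list was called lower without negative array 3 (0.0405) or positive array 1 (0.0131) and with cyclic loess (0.047).

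Markers of other cell types were used to look for signal of other cells, which was not separated from expression by the leukaemia itself. Plasma cell markers were lower as a list in MycGFP positive cells (camera adjusted p = 0.0115, and 0.277 with an estimated correlation), at a median log2 difference of -0.53. None of the 11 passed with limma, over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05. Mzb1 and Igha differed most, by log2 differences of -2.30 and -1.68 (adjusted p = 0.233 and 0.533), and Igha passed without negative array 3, at a log2 difference of -3.16 (adjusted p = 0.0429). The list was not called without positive array 2 (adjusted p = 0.109), with both arrays numbered 2 left out (0.0848) or by fry (0.167). Neutrophil and granulocyte markers were not called without the block (camera adjusted p = 0.075) and were called lower with it (adjusted p = 0.00172). None of the 18 passed with limma, over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05. On the scale of the negative mean this list lay at 2.18 on negative array 2 and 0.59 on positive array 2, and between -1.50 and -0.68 on the other arrays. Ngp and Pglyrp1 had the largest log2 differences, -1.64 and -1.50 (adjusted p = 0.681 and 0.441). The list was called lower without negative array 1 (0.0206), negative array 3 (0.00123), positive array 2 (0.00445) or both arrays numbered 3 (0.0103), and with array weights (0.0382). Its mean log2 difference turned from -0.62 to 0.47 without negative array 2.

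Among the lists of B cells, dendritic cells, natural killer cells and erythroid cells, 1 gene each passed, over all genes or adjusted over the list alone, and camera called none of the lists (adjusted p = 0.286, 0.362, 0.0988 and 0.628). Cd37, a tetraspanin gene that T cells also express, fell 2.33-fold, and Txk, a kinase gene of T and natural killer cells, fell 3.33-fold. Irf8, a transcription factor gene at intensities of 38.6 and 80.7, rose 2.06-fold, and Tfrc, the transferrin receptor gene, which is also on the MYC target list, rose 3.37-fold. The erythroid list had a median of -0.01 and a mean of 0.11, and the mean turned to -0.04 with each array centred on its median, to -0.17 without negative array 1, to -0.0058 without positive array 3 and to -0.18 without both arrays numbered 1. In the lists of macrophages, platelets and stromal cells none of 25, 12 and 19 genes passed with limma, over all genes or adjusted over the list alone, and camera gave adjusted p = 0.115, 0.138 and 0.148. At an unadjusted p under 0.05, 1 stromal gene was lower, and none of the macrophage or platelet genes differed. The largest log2 differences were -0.91 for Csf1r and -0.86 for Ccr2, -0.38 for Ppbp and -0.32 for Clec1b, and -1.05 for Col1a1 and -0.97 for Pecam1. Their adjusted p were 0.438, 0.630, 0.253, 0.353, 0.639 and 0.0904, and Pecam1 passed under the block (0.0416) and without negative array 3 (0.0466). Without positive array 1 the B cell (adjusted p = 0.0299), natural killer (0.0162) and macrophage (0.0393) lists were called lower. The natural killer list (0.0201) and the platelet list (0.0324) were called lower without negative array 2, and the macrophage list without negative array 3 (0.0138). The macrophage list was also called lower with both arrays numbered 1 (0.028) or numbered 3 (0.0492) left out and with array weights (0.0424), and the natural killer list with both arrays numbered 1 (0.0197) or numbered 2 (0.026) left out. The mean log2 difference of the B cell list turned from -0.12 to 0.16 without negative array 1 and to 0.03 without positive array 2, and that of the macrophage list from -0.19 to 0.08 without negative array 2 and to 0.04 without both arrays numbered 2.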

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

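The tests of this part were chosen after the values were seen, except the counts over other groupings of the arrays.

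Probe sets to which the annotation gives no single gene name take no part in the comparison of genes, and many of them differed between the groups. Of 10092 such probe sets, 151 were higher and 513 lower in MycGFP positive cells in the same limma test over all 45037 probe sets, and 2155 had an unadjusted p under 0.05. The share that passed was 6.58%, against 6.87% of the named probe sets, of which 1653 were higher and 748 lower. The 2 largest rises among them were log2 differences of 3.78 and 3.10 (adjusted p = 0.0189 and 0.0272). The 2 largest falls were log2 differences of -3.71 and -3.67 (adjusted p = 0.0347 and 0.0285).

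The 1115 genes called between the sorted groups compare with at most 3 in any other of the 10 splits of the 6 arrays into groups of 3, and 1 split of 10, the real one, reached that number. The 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 pairs of arrays, those other than the real one called no gene with limma, with 206 to 342 genes at an unadjusted p under 0.05 against 4015. Of the 10 splits, 2 gave the 18 called lists of the real groups. The other one, which calls 3 genes, sets both arrays numbered 1 and negative array 2 against the rest, and what gave its list calls was not tested. Among the splits that part all pairs the others called 10 to 15 lists.

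The mean of the ribosome biogenesis list, of which 26 of 56 genes passed, was higher by a similar amount on each positive array. Cycling genes, by the mean of the G2 and mitosis list, varied widely among the negative arrays. A higher share of cycling cells in the MycGFP positive sort might be thought to raise both. With the mean of the G2 and mitosis list on each array as a covariate, the group difference in the ribosome biogenesis mean was 1.25 with an SE of 0.11, against 1.04 with an SE of 0.09 without it. Leaving out any one array kept it at 1.17 to 1.35, though with an SE of 0.37 without negative array 1. That array had the highest cycling mean of its group, 1.29, and a ribosome biogenesis mean of -0.12. Among the negative arrays alone, the ribosome biogenesis mean did not rise with the cycling mean. The cycling means of the positive arrays, 1.91 to 2.54, all lay above 1.29, so the groups do not overlap in the covariate. The adjusted difference is thus an extrapolation and cannot exclude cycling for that list. With the covariate MYC targets differed by 1.02 with an SE of 0.18, close to 1.15 without it. Nucleotide metabolism differed by 1.04 with an SE of 0.20, close to 1.17 without it. Oxidative phosphorylation, at 0.42 with an SE of 0.24, and sterol and lipid synthesis, at 0.48 with an SE of 0.29, lay within 2 SE of 0. Cycling stays open for all of these lists. The covariate also moved lists that were not called, interferon response from -0.15 to -1.42 with an SE of 0.45, erythroid markers from 0.11 to 0.95 with an SE of 0.35 and the MYC-MAX network from -0.29 to 0.21 with an SE of 0.10, and raised glycolysis from 0.41 to 1.02, so values under it are uncertain with 6 arrays. Centring each array on the median over its genes took the same 0.15 from the difference of every gene. The list mean that remained, 0.891 with an SD of 0.607 over 56 genes, follows from this by arithmetic. A constant shift of 0.15 is smaller than the rise, but other effects of scaling between arrays were not tested. A difference in MYC between the sorted groups stays open as an untested explanation, and no gene was called by limma with the covariate, where 2755 had an unadjusted p under 0.05.

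Granulocyte transcripts stood out on both arrays numbered 2. S100a8 and S100a9 had intensities of 4467 and 4372 on negative array 2 and 871 and 1041 on positive array 2, against 26.2 to 675 on the other arrays. Granulocytes carried through the sort are a candidate source, although gates on CD25, mCherry and mononuclear cells should remove them. One source would keep its genes in proportion, and 78.6% of the 14 markers above the median of negative array 2, 11 of 14, of a list fixed before the data were examined, differed between the 2 arrays by within 1 log2 unit of their median difference of 2.09. Mpo, Wfdc21 and Pglyrp1, at log2 differences of 0.32, 0.37 and 3.24, lay outside. All genes above that median reached 75.9%, and 57.7% of 10000 random lists of 14 such genes did as well as the markers. Each list was set against its own median difference, so the share measures spread and leaves out the size of the shift. It cannot separate granulocytes from expression by the leukaemia, and both stay open.

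Y-linked transcripts also differed between sorted arrays of the same number. Eif2s3y had intensities of 3174 and 2127 on negative and positive array 1, 1038 and 125 on the arrays numbered 2, and 40.2 and 186 on those numbered 3, and Kdm5d and Uty had the same order within the numbers 2 and 3. On the arrays numbered 3, however, Kdm5d, at 6.39 and 17.6, and Uty, at 6.9 and 12.0, lay below the array medians. The order on the arrays numbered 3 thus rests on Eif2s3y. Xist, expressed in female cells, stayed between 11.04 and 19.7 on all 6 arrays, below the array medians. Its other probe sets lay at 4.33 to 11.4, so no array showed clear Xist signal. Granulocytes of a male recipient are a candidate source for the arrays numbered 2, where the 3 Y-linked genes had a mean log2 difference, negative minus positive, of 2.96. Kdm5d and Uty lay below the median of positive array 2, at 17.9 and 10.3, so their differences may be too small. Of the 3 genes only Eif2s3y lay above the median of both arrays. From that gene alone granulocytes and another source cannot be told apart. On the arrays numbered 3 the granulocyte markers differed by 0.000138, with an SE of 0.157 over the 14 markers of this single pair. Most of these markers lay below the array medians on both arrays, so their lack of a difference says little. S100a8 and S100a9 were only 42.7 and 27.2 on positive array 3, where Eif2s3y was 186, which argues against granulocytes there. Arrays of 1 number that come from different leukaemias, loss of the Y chromosome in part of a leukaemia, or other host cells were not tested and stay open.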

How the results depend on the processing

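Leaving out both arrays of a number was chosen after the data were seen. The direction of Myc and of the 93 other called named genes held in every setting, and none of the 35 lists reversed a call. For the settings that leave out arrays, the separated groups of these genes fix their direction in advance. Outside the settings that leave out arrays, 788 of 833 values for the 93 genes stayed past the threshold and 45 did not. The replicate number as a block gave 1047 higher and 354 lower genes, Myc at adjusted p = 0.0447 and 9 lower lists. It changed no call of Myc or a list other than the neutrophil list, and among called named genes ended those of Dhrs3, Gabbr1, Atp5b, Themis, Cd5, Rmnd5a and Phlda3, while Pecam1 passed. Leaving out 1 array at a time gave 0 to 862 higher and 0 to 238 lower genes, log2 differences of Myc of 1.1646 to 1.5156 with adjusted p of 0.0436 to 0.108, 9 to 11 higher lists and 8 to 14 lower lists. Fewer arrays leave fewer degrees of freedom, and why array 2 of the positive group matters most was not tested. Leaving out both arrays numbered 1 gave 310 higher and 42 lower genes and Myc at 1.1909. Without both numbered 2 limma called 0 and 0 genes, with 1728 higher and 759 lower at an unadjusted p under 0.05, and Myc was at 1.2585. Without both numbered 3 it called 0 and 0, with 2132 and 1055 unadjusted, and Myc was at 1.6466. In these 3 settings Myc had adjusted p = 0.108, 0.263 and 0.106. Median centring gave 502 higher genes. The median over the genes, on which it centred, was 5.67 to 5.685 on negative and 5.78 to 5.85 on positive arrays in log2. It thus lowers every positive value against the negative ones by construction. The median intensity over all probe sets was instead lower on the positive arrays, at 30.5 to 31.4 against 31.7 to 32.7. Centring on that median was not tested. Cyclic loess ended the calls of Rad54b, Ska1, Tcf7l2, Adamts6, Kif23 and Bid (adjusted p = 0.0501 to 0.0725), quantile normalization those of Rad54b, Tcf7l2 and Irf8 (0.0504 to 0.0544), a trended and robust variance those of Cd5, Itgal, Bid, Pdia6, Ctsd and Irf8 (0.0541 to 0.108), and array weights those of Tcf7l2 and Bid (0.0793 and 0.0507). Testing every probe set gave 585 lower genes, since a gene then passes through any of its probe sets. Camera with an estimated correlation called 0 higher and 0 lower lists. It allows for genes of a list that vary together, but whether that alone ended the calls was not tested. Signal over background limits the dim genes, and with the dimmest 40% left out 971 genes were higher and 319 lower.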

Other observations

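The lists and genes of this part were chosen after the results of the comparison had been seen, so their tests are not independent evidence.

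Among 24 genes of the nuclear pore and nuclear transport, 12 rose, including the export receptor gene Xpo1 at 2.67-fold, the import receptor genes Ipo5 and Kpna2 at 2.76-fold and 3.07-fold, and Nup133 at 3.23-fold higher (camera adjusted p = 4.07e-13 over 42 lists, and 0.0579 with an estimated correlation). Of 19 aminoacyl-tRNA synthetase genes, 8 rose, among them Vars at 3.70-fold and Gars at 2.35-fold (adjusted p = 5.03e-10, and 0.0694 with an estimated correlation). Of 25 genes for homologous recombination and the Fanconi pathway, 14 rose. Rad51c rose 6.64-fold, Dna2 6.59-fold, Brca2 5.71-fold and Brca1 5.22-fold (adjusted p = 4.07e-13, and 0.102 with an estimated correlation). Of 31 proteasome genes, 4 rose, at a list median of 0.55 on the log2 scale (adjusted p = 9.77e-10, and 0.222 with an estimated correlation). Of 26 translation initiation factor genes only Eif2b3 rose, 4.76-fold, at a list median of 0.48 (adjusted p = 2.77e-06, and 0.134 with an estimated correlation).

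Among 34 genes of T cell receptor signalling, 7 fell. These included Orai2, a calcium channel gene, at 3.50-fold, Bcl6, a transcriptional repressor gene, at 3.47-fold, the diacylglycerol kinase gene Dgka at 2.88-fold, the lipid phosphatase gene Inpp5d at 2.48-fold and Socs3 at 4.22-fold lower (camera adjusted p = 2.72e-08, and 0.0579 with an estimated correlation). Bcl6 went from a mean log2 intensity of 12.2 to 10.4. Chromatin modifier genes moved both ways, with 4 of 28 lower and 1 higher. The histone demethylase genes Kdm5b, Kdm7a, Jmjd1c and Phf8 were 6.29-fold, 2.78-fold, 2.75-fold and 1.46-fold lower, and the histone methyltransferase gene Suv39h2 rose 4.82-fold (adjusted p = 0.0282, and 0.388 with an estimated correlation). Fbxw7, whose ubiquitin ligase targets MYC and NOTCH1 for degradation, had a log2 difference of -1.03 (adjusted p = 0.117, and 0.0369 under the block). Pvt1, the neighbour of Myc, had a log2 difference of 3.12 (adjusted p = 0.0751, and 0.0489 under the block), from an intensity of 8.26, near background, to 107.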
